A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

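PAR-CLIP was performed on fission yeast (Schizosaccharomyces pombe) cells carrying Clr3, a histone deacetylase of the SHREC complex, with a TAP tag. Per the labels' protocols, cells were fed the uridine analogue 4-thiouracil at 30 °C in medium with 10 mg/l uracil and 4% glucose, first at 100 µM and then with a further 900 µM for 4 h. They were irradiated with 12 J/cm2 at 365 nm, the tagged protein was recovered on IgG beads, and the bound RNA was trimmed with RNase T1, which cuts after G. Reverse transcriptase reads a crosslinked 4-thiouridine as C, so a T-to-C change marks the contact nucleotide. The groups were taken from the sample titles and the series design: 2 crosslinked replicates and 1 control without crosslinking. The control's own description and protocol text are shared with the crosslinked samples and mention irradiation, so its status as a control rests on its title and on the series design. The remaining 6 RNA-seq samples (3 wild type and 3 seb1-1) had no processed files among those used and were not analysed here.

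Each library was one table of called positions. The authors' deposited counts are, for each position, the number of reads with a T-to-C conversion and the number of reads covering it; the column names are single letters per the file headers, and this reading rests on the values, since conversions never exceeded reads and each nuclear position was a T on the given strand. The authors' deposited p-value is the p of each call, named so per the file headers, with a highest value of 0.00499 in crosslinked replicate 1, 0.00495 in crosslinked replicate 2 and 0.00497 in the control. The authors' deposited occupancy is a ratio, the conversions divided by a whole number that was the same in both crosslinked libraries at all 276 positions they shared. That number was read as the depth of a separate reference library, which is not named in the sources used here, and it is called the reference depth below. Per the submitters' processing notes, Bowtie 1.1.1 and SAMtools were used for the PAR-CLIP samples with genome build ASM294v2. The site caller, its thresholds and the treatment of reads with several matches are not given in the sources used here. Only called positions with at least 3 reads are listed, so library depth is unknown, and sums of reads or conversions cover called positions alone.

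Positions were matched to the supplied reference genome and annotation of the same species. The positions called on nuclear chromosomes were all at a T there: 6560 of 6560 in crosslinked replicate 1, 4742 of 4742 in crosslinked replicate 2 and 127 of 127 in the control. Mitochondrial coordinates did not match the reference sequence and were left out of the comparisons, as were positions on the contig AB325691. Each nuclear site was given 1 class, in the order rRNA, tRNA, snRNA, snoRNA, other structural RNA, mRNA, ncRNA, antisense to a gene, intergenic. Genes with near-identical copies, among them tRNA, rRNA, histone, Tf2 and several ribosomal protein genes, can share reads, and their values are uncertain for that reason.

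The tests, the gene lists, the motifs, the rule for named genes and most alternatives were chosen before the data were examined. Across libraries no test was made, because 2 libraries against 1 allow no exact permutation p below 1 in 3. Overlap of the replicates was compared with 1000 draws that moved each site of crosslinked replicate 2 to a random T of the same gene and strand (one-sided permutation test). Position along mRNAs was compared with 1000 draws of a random T of the same spliced mRNA, and motifs within 20 nt, bases within 10 nt and 4-mers with 1000 draws of a random T of the same gene, strand and gene part (two-sided permutation tests). The smallest p these draws can give is 0.001 one-sided and 0.002 two-sided. The 13 gene lists were tested by the two-sided Fisher exact test, as the number of protein-coding members with a sense site in both crosslinked libraries against all other protein-coding genes. Benjamini-Hochberg adjustment was made over lists, over the 7 motifs, over bases and positions, and over all 4-mers, with a threshold of 0.05. Single positions shared with the control were compared by the Fisher exact test on reads, which compares those libraries and not the conditions. Shares of counts carry 95% Wilson intervals. Reads were not counted by molecular identifier, so these intervals cover counting error only. The labels do not say that the crosslinked replicates came from separate cultures, so the SD of 2 values may measure technical spread alone. The p-values rest on drawn positions, on genes or on reads of these libraries and do not measure the spread between replicates.

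Named genes followed a fixed rule: the 12 protein-coding genes and the 10 ncRNA, snRNA, snoRNA or structural RNA genes with the highest mean share of conversions and at least 2 sites in each crosslinked library; the 10 shared positions with most conversions outside rRNA and tRNA; up to 10 members of the phosphate, meiotic and RNA 3' end lists with a site in both; pho1, tgp1 and the transcripts upstream of them; and up to 5 genes with a site in the control alone. Other genes are named as examples from the fixed lists, in order of conversions, or are said to have been chosen after their values were seen. Alternatives included the sites with the authors' p below the library's median, a coverage of at least 20 reads, each crosslinked library alone, other windows, GC-matched draws, length-matched random lists (10000 draws) and, added after the data were seen, sites with at least 2 conversions.

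The procedures were tested on simulated data. With sites moved at random, 4.64% of 280 motif tests, 5.83% of 120 position tests and 5.0% of 20 overlap tests passed 0.05, each run on up to 6321 sites. Planted UGUA motifs, planted shared positions and planted 3'UTR sites were recovered in 100.0% of 40, 20 and 20 runs. The motif and 3'UTR plants moved about 20% of sites, and 100 positions were planted as shared. Smaller effects were not planted. The random sites came from the same draws as the tests use, so these runs do not cover uneven coverage. Of 1000 random lists of 20 genes 2.9% passed, and of 1000 lists with sites in 75 percent of members 98.5% passed. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.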

Results

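RNA recovered with TAP-tagged Clr3, the histone deacetylase of the fission yeast SHREC silencing complex, was examined by PAR-CLIP. There were 2 crosslinked replicates and 1 library made without crosslinking. No PAR-CLIP library from untagged cells was among the samples. Contacts of Clr3 thus cannot be told from crosslinks of other proteins that may have been recovered on the beads. Crosslinked replicate 1 held 6661 called positions with 19348 T-to-C conversions among 613498 reads. Crosslinked replicate 2 held 4824 positions with 11134 conversions among 273082 reads. The no-crosslink library held 135 positions with 919 conversions among 15545 reads. Only called positions are listed, so the total depth of each library is unknown. Many calls rested on 1 converted read of 3: 3401 positions in crosslinked replicate 1 (51.1%, Wilson 95% interval 49.9 to 52.3), 3093 in crosslinked replicate 2 (64.1%, 62.8 to 65.5) and 0 of 135 in the control. The authors' p of such a call was 0.00467 and 0.00463, near the highest p of any call. Calls with 2 conversions reached 67 and 68 reads in the crosslinked libraries but 52 in the control. The control may thus have been called on stricter terms, under which 1 read in 3 could not pass. Shares of sites, and counts of 0 in the control, are limited by this. Positions with at least 2 conversions numbered 3260, 1731 and 135. The median conversion over these was 4.17% of reads in crosslinked replicate 1, 4.55% in crosslinked replicate 2 and 7.32% in the control. Over all nuclear positions it was 33.3% in both crosslinked libraries (SD 0.0, n = 2), the value of 1 read in 3, and 7.14% in the control.

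To find which RNAs carried the conversions, sites were assigned to transcript classes. Messenger RNAs held 87.5% ± 1.1 of the nuclear sites (SD, n = 2) and 55.4% ± 1.62 of the conversions in the crosslinked libraries, against 55.1% of sites (46.4 to 63.5) and 18.1% of conversions (15.7 to 20.8) without crosslinking. Transfer RNAs went the other way, with 19.6% ± 0.924 of conversions after crosslinking and 62.0% (58.8 to 65.2) in the control. These are shares: called tRNA sites numbered 219 and 176 against 39 in the control, with 3746 and 2017 conversions against 549. Spliceosomal snRNAs held 4.26% ± 0.169 of conversions and had 0 sites in the control. Small nucleolar RNAs held 4.15% ± 0.488 against 2.83% (1.92 to 4.14) in the control, and the other structural RNAs, chiefly the 7SL RNA of the signal recognition particle, 9.11% ± 0.8 against 5.31% (4.02 to 6.99). Annotated non-coding RNAs spanned 24.4% of the T positions of the genome by this assignment and held 2.3% ± 0.462 of conversions, while mRNAs spanned 42.0%. No test across libraries was made, since 2 libraries against 1 allow no exact permutation p below 1 in 3. At positions with at least 2 conversions, an alternative chosen after the data were seen, mRNAs held 79.1% of sites and 43.5% of conversions. The control, which has no calls of 1 read in 3, stays at 55.1% and 18.1% there, so the contrast is smaller.

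**Figure D1:**
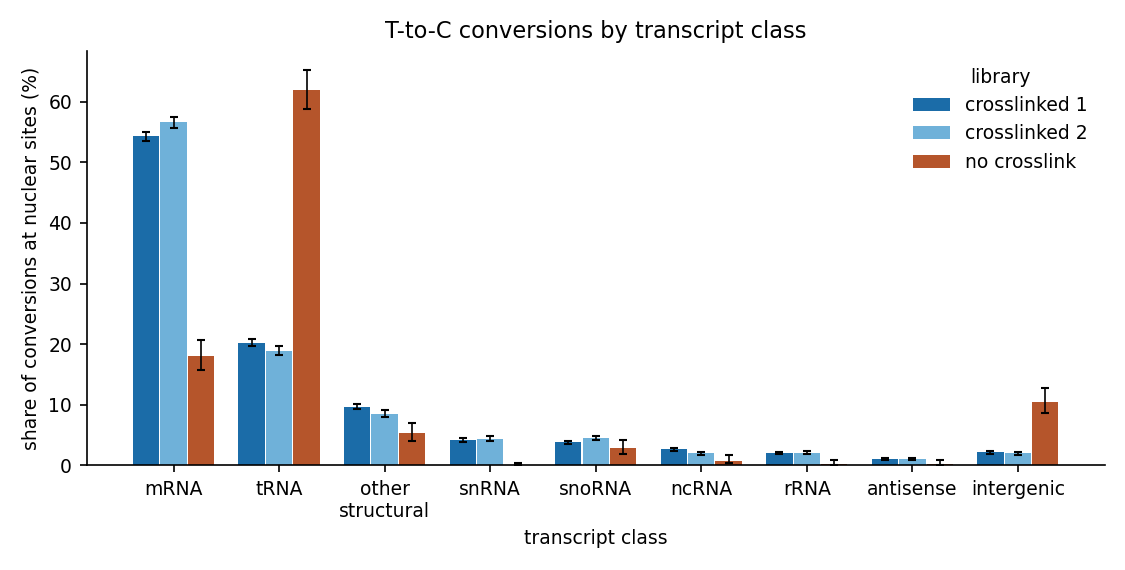
Share of T-to-C conversions at nuclear sites (%, y axis) by transcript class (x axis) in both crosslinked libraries and the no-crosslink library; bars are single libraries and error bars their 95% Wilson intervals. Messenger RNA took 54.3% and 56.6% of conversions after crosslinking and 18.1% without, whereas tRNA took 20.2%, 18.9% and 62.0%.

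Among protein-coding genes, the 12 with most conversions included a proton pump, chaperones, enzymes of glycolysis and fermentation, a vacuolar carboxypeptidase and an RNase P subunit. pma1, the plasma membrane proton pump (chromosome I, 3871642 to 3876111, minus strand), held 0.806% ± 0.172 of conversions (SD, n = 2), from 24 sites in crosslinked replicate 1 and 28 in crosslinked replicate 2. ssa2, an Hsp70 chaperone (III, 2057043 to 2059331, plus), held 0.576% ± 0.0065 from 25 and 17 sites. tdh1, glyceraldehyde-3-phosphate dehydrogenase (II, 2807595 to 2809051, plus), held 0.534% ± 0.0389 from 16 and 13 sites and had 0 sites in the control. pdc101, pyruvate decarboxylase (I, 101715 to 103597, minus), held 0.463% ± 0.0603 and also had 4 sites in the control, where it took 1.47% of conversions. Next came cpy1 with 0.401% ± 0.0948 and pop5 with 0.392% ± 0.0284. The hsp90 chaperone held 0.382% ± 0.00959, the pyrimidine synthesis enzyme ura1 0.353% ± 0.11 and the translation elongation factor tef3 0.335% ± 0.0901. In the control tef3 had 2 sites with 0.452% of conversions, pma1, ssa2 and adh1 had 1 site each with 0.226%, and hsp90 and ura1 had 0. The remaining members of these 12 were adh1, pfl2 and fba1. Values for adh1 (0.173% and 0.534%), fba1 (0.167% and 0.459%) and pfl2 (0.48% and 0.187%) lay far apart in the replicates. In cpy1, vacuolar carboxypeptidase Y, 51 of 62 and 35 of 50 conversions came from a single coding position, I 4063361, converted in 51 of 51 and 35 of 35 reads and in 9 of 10 control reads. Most conversions of cpy1 thus came from a position that also converted without crosslinking, and its rank here is no measure of contact. In pop5, an RNase P and MRP protein subunit gene, all 5 and 6 sites lay in an annotated intron.

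Of all 5113 protein-coding genes, 1525 (29.8%) had a sense site in both crosslinked libraries, but only 410 had one with at least 2 conversions in both. By the first count, each fixed gene list was compared with the genes outside it (28.9% to 29.9%, depending on the list). Sites were more frequent in ribosomal protein genes, with 86 of 138 members (62.3%, adjusted Fisher exact p = 1.74e-14). The members with most conversions included rpl8 with 14 and 25 conversions and rpl501 with 26 and 11. All 14 of the 14 glycolysis and ethanol genes had sites in both (100.0%, adjusted exact p = 2.75e-07), among them pgk1, phosphoglycerate kinase, with 47 and 39 conversions. Amino acid and nucleotide synthesis genes reached 25 of 34 (73.5%, 7.26e-07), led by ura1 and by met26, methionine synthase, with 46 and 39 conversions. Chaperones reached 16 of 21 (76.2%, 4.82e-05), with sks2, a ribosome-associated Hsp70, at 46 and 28 conversions. Translation factors reached 8 of 11 (72.7%, 0.0106), histones 7 of 11 (63.6%, 0.0386), stress response genes 10 of 18 (55.6%, 0.0499), and transporters and cell wall genes 13 of 26 (50.0%, 0.0499). Tf2 retrotransposons, whose copies are nearly identical and can share reads, were lower, with 0 of 13 (0.0%, 0.0298). Iron and copper genes (4 of 14, adjusted exact p = 1.0) did not differ from the background by this test. Of the 13 lists 9 passed, 8 higher and 1 lower. The test reads RNA abundance and binding together, since no RNA-seq values were used here. The transporter call was lost against length-matched lists (adjusted permutation p = 0.586), and histones with either replicate alone (0.0872 and 0.111); transporter, stress and translation factor calls were lost without crosslinked replicate 2 (0.257, 0.147 and 0.257). Tf2 stayed lower against length-matched lists (0 of 13 against 61.6%, adjusted permutation p = 5.2e-04) and with single replicates (adjusted exact p = 0.00245 and 2.88e-04), and 13 members are too few for a lower call at a coverage of at least 20 reads, with at least 2 sites in both or with at least 2 conversions (adjusted exact p = 1.0, 0.68 and 0.621). These p-values count the near-identical Tf2 copies as independent genes, which they are not. The p-values of the ribosomal protein and histone lists have the same limit, since several of their members are near-identical copies. If reads with several matches were dropped, 0 of 13 could follow whatever the binding, so the lower call decides nothing about Tf2.

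The series title concerns interference by non-coding transcription, and the phosphate-responsive gene pho1, an acid phosphatase repressed by the upstream transcript prt, is a known case in fission yeast. pho1 (II, 4447506 to 4449053, plus) had 3 sites with 7 conversions in 165 reads in crosslinked replicate 1 and 2 sites with 4 conversions in 59 reads in crosslinked replicate 2, none at the same position, and 0 in the control. It held 0.0376% ± 1.96e-04 of conversions (SD, n = 2). With only 7 and 4 conversions, this small SD does not cover counting error and is no sign of reproducibility. prt, annotated as nc-pho1 (II, 4446359 to 4448918, plus), overlaps pho1, and all of these sites fell in the overlap. The 1147 nt of prt upstream of pho1, with 420 T positions, held 0 sites in any of the 3 libraries. tgp1, a glycerophosphodiester transporter gene (II, 350310 to 352411, minus), had 1 and 2 sites, each of 1 converted read in 3, and nc-tgp1 upstream of it (II, 352335 to 354234, minus) had 2 and 1. pho84, a phosphate transporter gene, had 4 sites in crosslinked replicate 1, 0 in crosslinked replicate 2 and 1 in the control. In all 4 of 9 coding members of the phosphate list had sites in both crosslinked libraries (44.4% against 29.8%, adjusted Fisher exact p = 0.504), among them snz1 with 10 conversions and 1. Since only called positions are listed, a count of 0 sets no upper limit on binding.

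**Figure D2:**
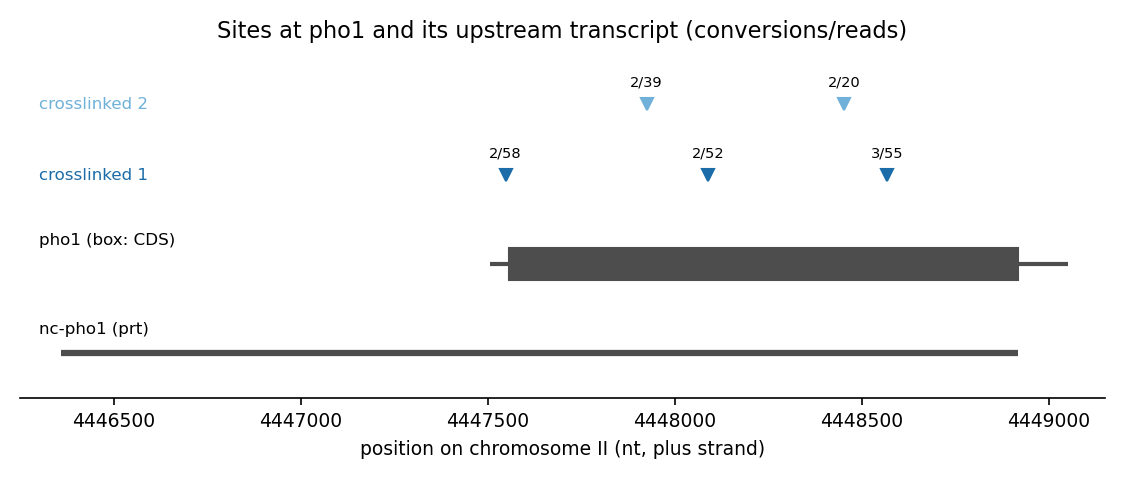
Called sites at pho1 and the overlapping upstream transcript nc-pho1 (prt) along chromosome II (x axis, nt, plus strand); triangles mark sites of the 2 crosslinked libraries with conversions over reads, the box is the coding sequence and thin lines are transcripts. The 3 sites of crosslinked replicate 1 and the 2 of crosslinked replicate 2 lie within pho1, and the upstream part of prt holds 0.

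Meiotic genes, many of them marked for decay by the RNA-binding protein Mmi1, had sites in both crosslinked libraries in 5 of 33 coding members (15.2% against 29.9%, adjusted Fisher exact p = 0.109). These were ste11, the transcription factor that starts sexual differentiation, with 9 and 2 conversions, the dynein heavy chain dhc1 with 3 and 5, mug8 with 4 and 3, spo3 with 3 and 2, and mei2 with 1 and 1. RNA 3' end processing and silencing genes reached 9 of 22 (40.9% against 29.8%, 0.297). They included cft1 and pla1 of the cleavage and polyadenylation machinery with 6 and 2 and with 4 and 1 conversions, red1 of the Mmi1 pathway with 4 and 2, and clr2 of SHREC with 2 and 3. The meiotic list was lower with a single replicate (adjusted exact p = 0.00882 without replicate 1 and 0.00942 without replicate 2), and the 3' end list was higher without replicate 2 (0.00942). At a coverage of at least 20 reads or with at least 2 conversions, 0 of 33 meiotic genes (adjusted exact p = 0.375 and 0.155) and 0 of 22 RNA 3' end genes (0.751 and 0.328) had sites in both, and with at least 2 sites in both the meiotic list stood at 12.1% against 9.53% (0.68).

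Structural RNAs and heterochromatic regions were examined because SHREC acts in heterochromatin. The 11 fixed structural RNAs held 15.01% ± 0.252 of conversions (SD, n = 2) and 5.76% in the control. The 7SL RNA srp7 (I, 4268662 to 4268916, plus) alone held 8.15% ± 0.906, against 5.31% (4.02 to 6.99) in the control. Its main position, I 4268794, was converted in 13.7% of 5437 reads (12.8 to 14.6) and 15.03% of 2455 reads (13.7 to 16.5), and in 1.91% of 2457 control reads (1.44 to 2.53; adjusted Fisher exact p = 1.41e-72 and 7.42e-67 between these libraries). U6 snRNA, snu6 (I, 2562276 to 2562419, minus), held 2.19% ± 0.254, mostly at I 2562375, converted in 2.41% of 14837 reads (2.17 to 2.67) and 2.85% of 8150 reads (2.51 to 3.23). The U3 snoRNA genes snu32 and snu3 held 0.933% ± 0.138 and 0.73% ± 0.239, and the RNase P RNA rrk1 0.832% ± 0.109 from 16 and 17 sites. The other spliceosomal RNAs were close together, with snu5 at 0.564% ± 0.0503, snu4 at 0.533% ± 0.0286, snu2 at 0.495% ± 0.0244 and snu1 at 0.453% ± 0.137. The non-coding RNA SPNCRNA.942 (I, 3851024 to 3851310, plus) held 0.381% ± 0.0579. Telomerase RNA, ter1, had 0 and 1 sites.

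Regions around heterochromatin (5 in number: 3 centromeres, the mating type region and the ends of chromosomes I and II) were set by fixed bounds. These bounds reach into flanking genes such as per1 and rpp202. Outside tRNAs they held 11 sites in crosslinked replicate 1, 12 in crosslinked replicate 2 and 0 in the control. The 40 kb at each end of chromosomes I and II held 0 in each library. The ends of chromosome III were not included. Near its right end, at 2442598 and 2443353 of 2452883 nt, SPRRNA.46 and SPRRNA.52 had sites in both crosslinked libraries. The centromeric regions held 2 and 3 sites of 1 conversion each, part of them in per1 at the edge of the first. The mating type region held 9 and 9, of which 4 and 4 had at least 2 conversions. The genes there were examined after their values were seen: rpp202, a ribosomal protein gene (II, 2127990 to 2128467, minus), held 4 and 3 of these sites, and the rest were in other protein-coding genes or in SPNCRNA.1488 and SPNCRNA.388. Sites with at least 2 conversions numbered 4.0 on average. Reads from repeats can match several places, and how they were treated is not given in the sources used here.

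To see whether the replicates marked the same nucleotides, their sites in genes were overlaid. They shared 273 positions, against 72.0 on average and 99 at most in 1000 draws within the same genes (one-sided permutation p = 0.001, the smallest these draws can give). The draws took any T of a gene, covered by reads or not. Uneven coverage common to both libraries can thus raise the overlap, which the draws cannot tell from shared contacts. Transfer RNAs gave 112 shared positions against 38.1 drawn, mRNAs 60 against 16.2, snoRNAs 31 against 4.44, snRNAs 23 against 5.05, the other structural RNAs 15 against 2.09 and ncRNAs 13 against 1.19, each with the same p. Leaving out the control's positions gave 244 against 58.6. By contrast, positions of 1 converted read in 3 from crosslinked replicate 2 coincided with a site of crosslinked replicate 1 in 7 cases against 4.9 drawn (permutation p = 0.224). Over all nuclear sites the 276 shared positions were 4.21% of crosslinked replicate 1 and 5.82% of crosslinked replicate 2. Of these 269 had at least 2 conversions in both, or 16.3% of the sites of crosslinked replicate 2 with at least 2. Across 3670 genes with a site in either library, log2 conversions per gene correlated with a Spearman coefficient of 0.17 and a Pearson coefficient of 0.482. Genes absent from one library count as 0 there. Over the 1652 genes with a site in both, a choice that leaves these out, the coefficients were 0.56 and 0.8. Genes are not independent replicates, and the Spearman coefficient was 0.584 over 886 genes at a coverage of at least 20 reads and 0.0561 for numbers of sites.

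Of the 127 nuclear control positions, 41 (32.3%) were also called in crosslinked replicate 1 and 34 (26.8%) in crosslinked replicate 2, most of them in tRNAs (30 and 28). By the adjusted Fisher exact test between libraries, 6 and 7 tRNA positions were converted in a higher share of control reads. Only positions called in both libraries were tested, so most of the 219 and 176 crosslinked tRNA sites were left out. A position with little conversion in the control was not called there, so the counts in either direction can lean towards the control. In a tRNA-Tyr gene, SPBTRNATYR.04, II 3814615 was converted in 25.7% of 323 control reads (21.2 to 30.7) and in 8.55% of 585 and 12.9% of 248 crosslinked reads. In 3 and 4 cases the crosslinked share was higher, including srp7 and tRNA-Gly II 2069505 (4.6% and 5.87% against 1.44%). Genes with a site in the control alone numbered 5 of 97: the snoRNA sno12, the tRNA genes SPATRNAGLU.01 and SPBTRNASER.06, SPNCRNA.698 and the 5S rRNA gene SPRRNA.27, with 2 to 4 conversions each.

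**Figure D3:**
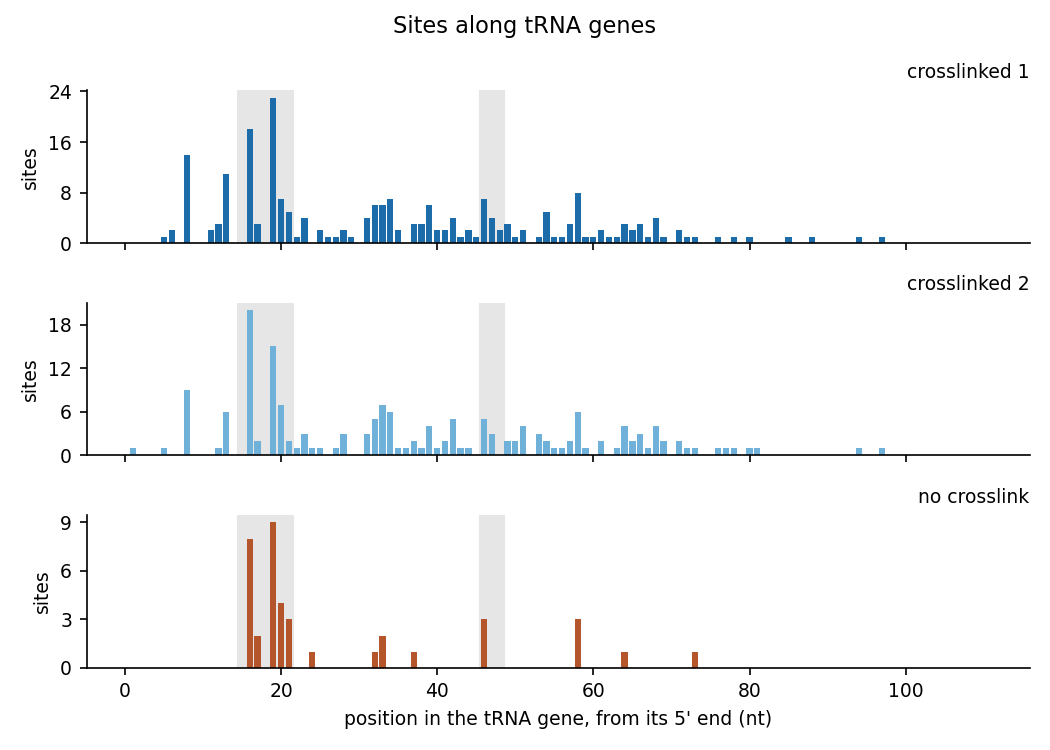
Number of called sites (y axis) at each position of the tRNA genes, counted from the 5' end (x axis, nt), in each library; shading marks positions 15 to 21 and 46 to 48, chosen after the sites were seen. The shaded positions hold 29 of 39 control sites, 69 of 219 in crosslinked replicate 1 and 54 of 176 in crosslinked replicate 2.

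Within mRNAs, sites were placed relative to the coding sequence (CDS) and untranslated regions (UTRs). In crosslinked replicate 1, 79.96% of 5595 exonic sites lay in the CDS, against 70.7% ± 0.555 of T positions drawn from the same mRNAs (SD over draws), and in crosslinked replicate 2 81.7% of 4121 against 70.5% ± 0.638. The 3'UTRs held 12.5% against 20.3% ± 0.482 and 10.9% against 20.8% ± 0.582. The 5'UTRs held 7.53% against 9.0% ± 0.36 and 7.4% against 8.68% ± 0.401. Each difference gave an adjusted two-sided permutation p of 0.002, the smallest these draws can give. The mean 5'UTR log2 ratio was -0.24 over all sites, -0.73 with a p below the library's median, -0.91 at a coverage of at least 20 reads and -0.75 with at least 2 conversions, and it passed in each (adjusted permutation p = 0.002). GC-matched draws, chosen after the data were seen and matched on broad classes of GC content, held fewer 5'UTR positions (7.98% ± 0.332 and 7.36% ± 0.345). Against them the 5'UTR ratio over all sites was -0.04 and no longer passed (adjusted permutation p = 0.168 and 0.939). At sites with at least 2 conversions it was -0.17, with 5.59% against 6.47% ± 0.41 in crosslinked replicate 1 and 5.4% against 5.9% ± 0.608 in crosslinked replicate 2 (adjusted permutation p = 0.04995 and 0.457). The CDS and 3'UTR differences passed in both settings (adjusted permutation p = 0.003), with the mean CDS log2 ratio falling from 0.19 to 0.11 over all sites and from 0.29 to 0.099 with at least 2 conversions. The mean 3'UTR log2 ratio was -0.82 over all sites, and -1.29, -1.35 and -1.27 under the stricter settings in the order above. GC matching brought it to -0.59 over all sites and to -0.68 with at least 2 conversions.

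**Figure D4:**
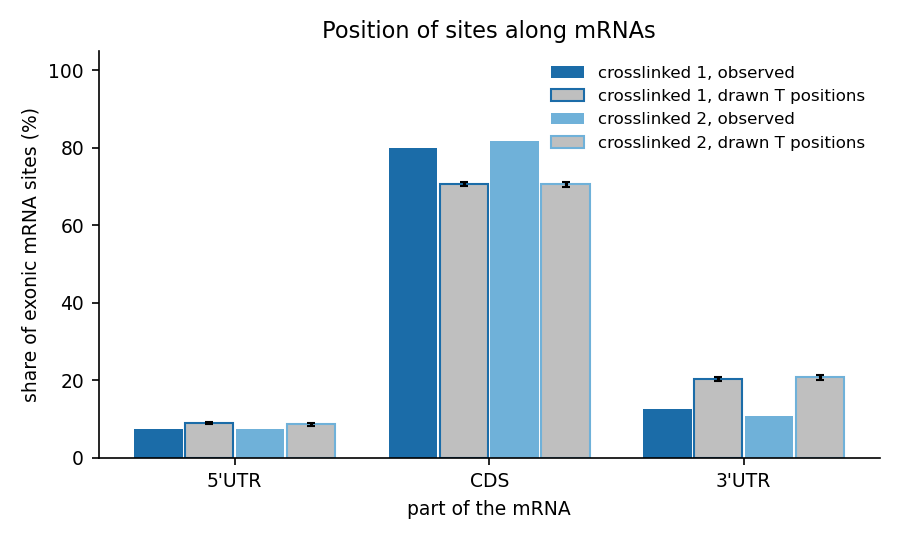
Share of exonic mRNA sites (%, y axis) in the 5'UTR, CDS and 3'UTR (x axis) for each crosslinked library, beside the mean of 1000 draws of T positions in the same mRNAs with bars of 1 SD over draws. The CDS holds 79.96% and 81.7% of sites against 70.7% and 70.5% drawn, and the 3'UTR 12.5% and 10.9% against 20.3% and 20.8%.

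Sequence motifs near the sites were tested because Seb1, the factor mutated in the RNA-seq samples of the series, is reported to bind GUA-containing RNA. GUA lay within 20 nt of 39.8% and 38.9% of sites, against 39.3% and 39.1% drawn (adjusted permutation p = 0.422 and 0.791), and UGUA near 14.2% and 14.0% against 13.8% and 13.8% (0.403 and 0.791). The Mmi1 motif UNAAAC was near 5.57% and 4.81% of sites against 5.29% and 5.35% drawn (0.403 and 0.199), and the polyadenylation signal AAUAAA near 2.17% and 1.6% against 1.98% and 1.91% (0.403 and 0.199). UUUUU was rarer than drawn, near 10.9% and 10.2% of sites against 13.9% and 13.7% (adjusted permutation p = 0.014 in both). Within 10 nt, GUA (23.2% against 21.9%, adjusted permutation p = 0.028) and AAUAAA (1.12% against 0.747%, 0.00699) passed in crosslinked replicate 1 but not in crosslinked replicate 2 (1.0 for both). The control motifs GUC and UGUC did not pass in both over all sites. In a single crosslinked library GUC passed in replicate 1 with a p below the library's median (adjusted permutation p = 0.035), and UGUC in replicate 1 at a coverage of at least 20 reads (0.042) and in replicate 2 without rRNA and tRNA (0.028). At the 273 shared positions GUC was near 50.9% against 42.2% drawn and UGUC near 15.8% against 9.79% (adjusted permutation p = 0.00466). Of these positions 112 lay in tRNAs. Neighbouring positions of one RNA, and near-identical gene copies, share the sequence searched. This p counts them as independent, which they are not.

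Of all possible 4-mers, 25 passed in both crosslinked libraries, 14 higher and 11 lower than drawn. AUGA was near 23.7% and 22.4% of sites against 19.7% and 19.6% drawn, and GACA near 11.1% and 11.5% against 9.44% and 9.41%. Pyrimidine runs were rarer, with UUUU near 29.7% and 29.7% of sites against 34.5% and 33.9%. Next to the converted U, A preceded it in 38.6% and 37.5% of all genic sites against 25.7% and 25.5% drawn, and G followed it in 31.3% and 30.9% against 23.1% and 23.3% (adjusted permutation p = 0.00622 and 0.00699 for both bases). At sites with at least 2 conversions, chosen after the data were seen, A preceded it in 40.4% and 36.7% of sites against 23.2% and 21.98% drawn, and G followed it in 36.3% and 36.8% against 25.4% and 26.2% (adjusted permutation p = 0.0073 and 0.012 for both bases). RNase T1 cuts after G, and its part in these values was not tested. The number of 4-mers was 15 with sites of a p below the library's median, 16 at a coverage of at least 20 reads, and 14 with at least 2 conversions. Of these 14, 5 were higher and 9 lower. GACA and UUUU were kept among them, and AUGA was not.

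**Figure D5:**
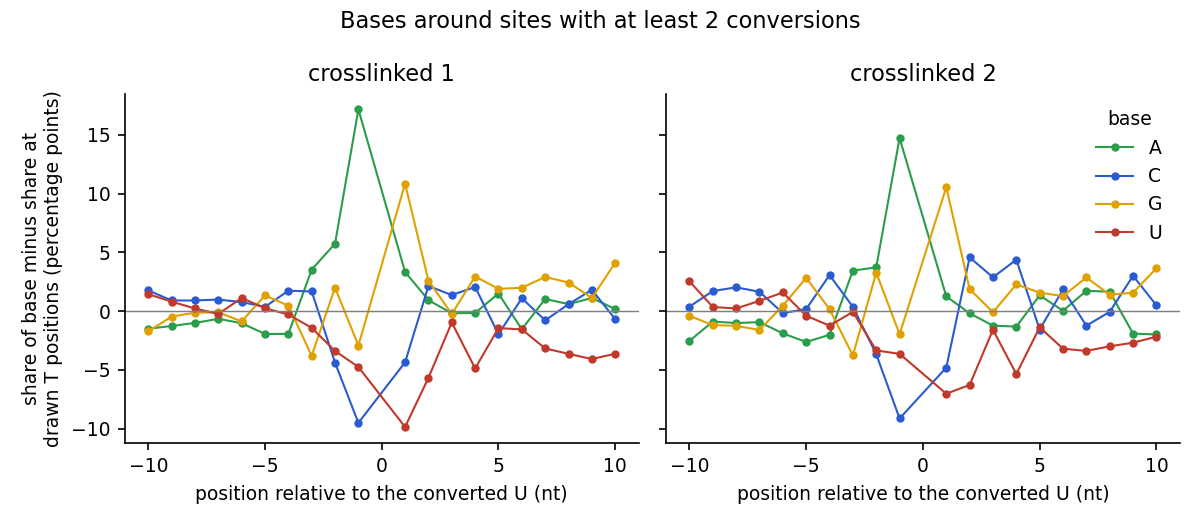
Share of each base at the sites minus its share at drawn T positions (percentage points, y axis) by position relative to the converted U (nt, x axis), for sites with at least 2 conversions in each crosslinked library. A at the preceding position (40.4% and 36.7% of sites against 23.2% and 21.98% drawn) and G at the following one (36.3% and 36.8% against 25.4% and 26.2%) stand highest.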

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

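No test was run on the values in this part, which were singled out only after they were seen. Mitochondrial RNA, outside every comparison because its coordinates did not match the reference, held 99 called positions with 807 conversions in crosslinked replicate 1 and 82 with 462 in crosslinked replicate 2, against 8 with 34 in the control. All lay on the plus strand. Library depth is unknown, so these counts alone show no excess after crosslinking: as a share of conversions they came to 4.17% (3.9 to 4.46) and 4.15% (3.8 to 4.54) against 3.7% (2.66 to 5.13), and as a share of called positions to 1.49% and 1.7% against 5.93% (3.03 to 11.3). The crosslinked calls include those of 1 read in 3, which the control lacks; among positions with at least 2 conversions the shares were 3.04% (2.5 to 3.68) and 4.51% (3.63 to 5.59). The contig AB325691 held 2 sites in crosslinked replicate 1 and 0 in the others.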

How the results depend on the processing

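Tests on sites with at least 2 conversions, motif tests on 1 site per gene or without rRNA and tRNA, GC-matched draws for mRNA position (on all sites and on those with at least 2 conversions) and the naming of genes without near-complete positions were chosen only after the result was seen. In all 286 alternatives were computed for 43 results. For summary results 119 kept direction and side of the threshold or stayed within the spread, 30 moved, 2 became stronger, 2 weaker and 13 turned sign; for single lists and classes these numbers were 88, 15, 3, 9 and 5. Each sign change was in a motif or list that passed neither originally nor under that alternative in both libraries. As mean log2 ratios, GUA turned to -0.010 with a window of 40 nt and -0.042 with 1 site per gene, UGUA to -0.022 and -0.035, UNAAAC to 0.065 with 10 nt, 0.054 with 40 nt and 0.035 with 1 site per gene, AAUAAA to 0.358 with 10 nt and 0.011 with GC-matched draws, and GUC to -0.013 with 10 nt; with single replicates GUA ranged from -0.0082 to 0.018, UNAAAC from -0.153 to 0.074 and AAUAAA from -0.256 to 0.128. In percentage points against other genes, meiotic genes turned to 2.59 with at least 2 sites in both, RNA 3' end genes to -5.81 at a coverage of at least 20 and -8.05 with at least 2 conversions, and iron and copper genes to 4.94 and 13.7 with single replicates; the cause was not tested. Requiring a p below the library's median, a coverage of at least 20 or at least 2 conversions, in that order, gave 3159, 2661 and 3260 sites in crosslinked replicate 1 and 1689, 1382 and 1731 in crosslinked replicate 2, a median conversion of 4.55%, 3.67% and 4.39%, mRNA shares of 78.9%, 76.4% and 79.1% of sites and 42.9%, 39.2% and 43.5% of conversions, structural RNA shares of 19.98%, 21.6% and 19.7% of conversions, sites in the regions around heterochromatin of 3.5, 3.5 and 4.0 on average, and 15, 16 and 14 4-mers. The p threshold left 67 control sites. Each of these settings removes all calls of 1 read in 3. The gene correlation was 0.584 at a coverage of at least 20, 0.44 with at least 2 conversions and 0.0561 for numbers of sites. GC-matched draws brought the 5'UTR log2 ratio to -0.038, and to -0.17 at sites with at least 2 conversions, and shared positions alone brought GUC to 0.27 and UGUC to 0.68; the cause was not tested. With single replicates the 4-mers past the threshold ranged from 42 to 69, since passing in both was not required, and lists past it from 7 to 9, while mRNA held 86.8% to 88.3% of sites. Of the 22 top genes, 19 to 20 were kept with single replicates and 18 when ranked by reads. No value was obtained with a replicate left out for the overlap and the gene correlation, which need both. No paired analysis was possible because the crosslinked and control groups share at most 1 replicate number, and the wild type and seb1-1 RNA-seq samples, which share 3, had no files here; their comparison was not run. Unknown library depth limits every comparison of site numbers between libraries.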

Other observations

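The tests below on tRNA positions and on calls of 1 read in 3 were chosen only after the result was seen, and the genes and positions here were picked from their values; the other tests were specified before their own values were computed, but after the patterns they address were known. Introns held 97 and 67 sites, of which 19 and 16 had at least 2 conversions, and 0 in the control. Within the pop5 intron 5 positions recurred in both replicates, such as III 2197948 with 17 conversions in 854 reads and 16 in 321. The meiotic regulatory RNA mamRNA (II, 1307681 to 1308359, plus) had 6 and 7 sites with at least 2 conversions, and 1 position in both, II 1308335, at 1.42% of 773 reads (0.796 to 2.53) and 1.93% of 311 reads (0.887 to 4.14). SPNCRNA.87 (I, 3177931 to 3178309, plus) had 9 and 5 sites, among them I 3177946, converted in 5.73% of 227 reads (3.38 to 9.55) and 5.16% of 97 reads (2.22 to 11.5). The telomerase, sme2 and nam1 RNAs had at most 2 sites per library.

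At 5 positions at least 80% of reads were converted in both crosslinked libraries, and 2 of them were also called in the control. At II 257526, between genes and downstream of the tagged gene clr3 (II, 254686 to 257138, plus), 255 of 285, 133 of 142 and 87 of 91 control reads were converted. The others were cpy1 I 4063361, also called in the control, SPRRNA.46, SPRRNA.52 and mgs1 I 4118942. At the 2 positions called in the control, conversion was near complete without crosslinking too, which argues against a crosslink as its source there. What caused these conversions was not tested. The clr3 mRNA itself had 3 and 1 sites, each of 1 converted read in 3.

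In the control, tRNAs converted without crosslinking at recurrent places. Of 39 control tRNA sites 29 (74.4%, 58.9 to 85.4) lay at gene positions 15 to 21 or 46 to 48. Those windows were chosen from the same sites, so this share decides nothing about misreading of modified bases by reverse transcriptase, which stays open. Gene positions only approximate standard tRNA numbering. A DNA difference between strain and reference is argued against, since the highest conversion there was 42.9% over 13 isotypes. No biological explanation was tested, and the crosslinked libraries had 31.5% and 30.7% of tRNA sites in these windows.

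Sites in mRNAs lay in the CDS more and in the 3'UTR less than drawn T positions. Calls of 1 read in 3 are argued against as the source, since at sites with at least 2 conversions the CDS log2 ratio was 0.29 and passed in both libraries. Annotated 3'UTRs that reach beyond the transcripts are argued against as the whole source by the 100 nt flanking stop codons of 4132 mRNAs. There, sites per T in the 3'UTR were 0.626 (0.525 to 0.745) and 0.56 (0.454 to 0.689) of those in the CDS. These ratios were not matched on GC content, and they do not exclude that such annotation adds to the deficit further downstream. Against GC-matched draws the 3'UTR log2 ratio moved from -0.82 to -0.59, and from -1.27 to -0.68 at sites with at least 2 conversions. It stayed past the threshold in both libraries each time. The match used only 3 broad classes of GC content, so differences in GC within a class remained. GC content can thus account for part of the deficit, and these draws do not exclude low GC content as the whole cause. Finer sequence preferences and a real preference of Clr3 for coding sequence stay open, and no group of the design tests the latter.

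The mRNAs with most conversions may be the most abundant ones: 9 of the 12 lay above the 90th percentile of reference depth among 3370 mRNAs with a site, exactly the number set beforehand as the lower bound. The 9 include cpy1 at percentile 92.7, most of whose conversions came from a position also converted in the control. pop5, pfl2 and ura1 lay below the 90th percentile, at 80.3, 81.6 and 88.1, and the depth of pop5 is that of intron positions. Across mRNA sites with at least 2 conversions, reads correlated with reference depth with a Spearman coefficient of 0.643 and 0.584; sites are not independent replicates. The reference library is not named in the sources used here, so its depth stands in for abundance only if it was an RNA library of comparable cells. No biological explanation was tested.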
